A study of Mus musculus with 2 samples.

How the data were processed

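Spatial transcriptomes were collected from formalin-fixed, paraffin-embedded small intestine of wild-type C57BL/6 mice with the 10x Genomics Visium HD assay, in which probe pairs that hybridise to the transcripts of a gene panel are captured on a slide carrying a continuous grid of barcoded squares. Per the labels, sections were 5 µm thick, the probes were those of the mouse transcriptome kit, version v2, and there were 2 samples, 1 from a mouse on the control diet and 1 from a mouse on the stearic acid-rich high-fat diet (HFD). The submitters' processing notes name Space Ranger, the assay maker's pipeline, and the genome build mm10. The pipeline version, its parameters and the way bins were called as lying over tissue are not given in the sources used here.

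The 6 files used here were 3 per sample. The authors deposited a list of barcodes, a gene table and a set of 7 image scale values for each section. Each barcode is the name of a square bin and carries its size, its grid row and its grid column. Every name in both lists had the 8 µm size and occurred once. The gene table pairs an Ensembl identifier with a symbol. Per-bin transcript counts were not analysed here, so no expression level, fold change, cell type assignment or sequencing depth is given, and the expression comparison set out in the design was not made. What was measured is the ground over which expression was read, that is, the outline of the tissue on the capture grid, and the genes that the table lists.

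The barcodes were placed on a grid of 838 by 838 positions (702244 in all, 6.704 mm per side), rows and columns being counted from 0 and the highest number in either list being 837. The following measures of the outline were set before the data were examined. The covered share is the share of grid positions with a barcode. The edge share is the share of covered bins with at least 1 uncovered bin among their 4 side neighbours. The deep share is the share of covered bins whose centre lies more than 40 µm from the centre of the nearest uncovered bin. Pieces are groups of at least 100 covered bins in contact through any of 8 neighbours. The enclosed gap share is the area of uncovered bins cut off from the frame of the grid by tissue, as a share of covered plus enclosed bins. Positions outside the grid were counted neither as tissue nor as gap, so a gap that runs off the frame is not counted as enclosed. Shares carry exact Clopper-Pearson 95% intervals, which treat bins as independent and cover the counting of bins only. Neighbouring bins are not independent, so part of the spread within a section is also given. It is the lowest and highest value over 4 equal blocks of grid columns (column blocks), a description added after the maps were seen. The ranges over column blocks describe 1 section each and are not replicate errors. In both sections the tissue lay in bands parallel to the grid rows, so each column block cuts across bands. The ranges therefore leave out variation between bands.

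With 1 section per diet there is no test between diets, and no p-value is given. Alternatives filled gaps of 1 bin, kept only pieces of at least 100 bins, joined bins 2 by 2 into 16 µm bins (covered when at least 2 of 4 were, with pieces of at least 25 joined bins), left out the outer 20 rows and columns, used 8 neighbours for edges or 4 for pieces, set depth at 24 or 80 µm, set the smallest piece at 10 or 1000 bins, and ignored letter case in gene symbols. An alternative chosen after seeing the data kept only the grid rows from the first to the last with at least 50% of columns covered, which is a choice by cover itself. The measures were tested on simulated masks with known answers, and 14 of 14 checks matched.

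Genes were looked up by symbol in the gene table, so a gene listed only under another symbol counts as one without a row. A total of 25 lists with 159 entries, 7 of gene functions and 18 of cell type markers, were fixed before the data were examined, and by the rule for named genes every member without a row is named, with examples of those that have one. Genes outside these lists were chosen after the table was seen. Coordinates are those of RefSeq genes on GRCm38.p6, the assembly that mm10 stands for. Of the 19053 distinct symbols in the table, 18859 were found there. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, and figures were drawn with matplotlib 3.10.9.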

Results

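The study compared the small intestine of mice fed a control diet, with 10% of energy from fat, with that of mice fed a high-fat diet rich in stearic acid, a saturated long-chain fatty acid, with 54.8% of energy from fat. Diets were started at 4 weeks of age, and the tissue was fixed after 2 weeks of HFD feeding. No time on the diet was recorded here for the control mouse. There was 1 section per diet. The control section was represented by 500025 tissue-covered bins of 8 µm, or 32.0 mm² of tissue, and the HFD section by 570718 bins, or 36.5 mm². Image resolution was close in both sections, at 0.378 µm per pixel in each. Transcript counts were not analysed here, and the depth per bin is therefore unknown.

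In both sections the tissue lay in long bands parallel to the grid rows, separated by open strips and by rows of narrow gaps. The bands reached both sides of the grid. The control section touched 609 bins of the left column and 576 of the right, and the HFD section 745 and 620. In the first and last grid rows the control section touched 0 and 70 bins, and the HFD section 202 and 557. Neither section was therefore captured whole, and the values below describe the part of the intestine that lay on the grid. The HFD section met the frame in more bins on every side, and the frame counts neither as edge nor as open space. How far this unequal contact shifts the edge, deep and enclosed gap shares was not measured. The control section left the first grid rows open, and its rows reached 50% cover from row 106 (counted from 0), whereas the HFD section reached it from row 12.

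**Figure D1:**
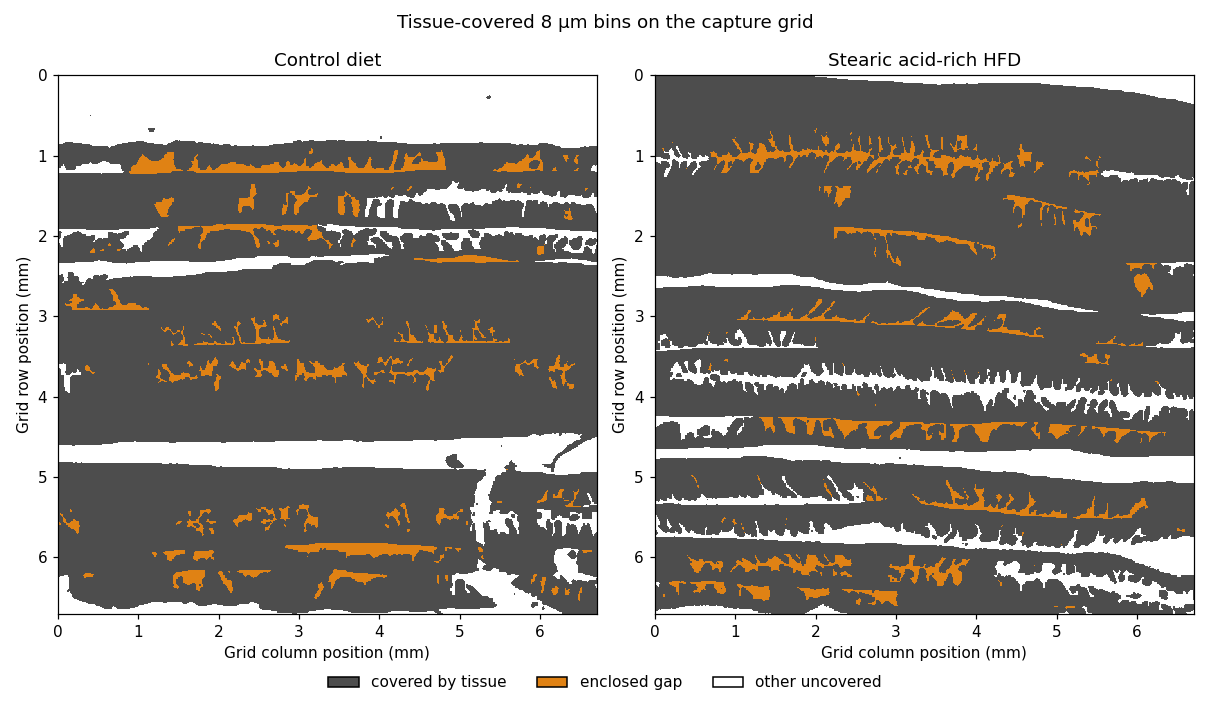
Map of the tissue-covered bins (dark) in the control and HFD sections, drawn to scale with grid column and row positions in mm. Enclosed gaps (orange) made up 6.57% of the control outline and 6.03% of the HFD outline, and white marks all other uncovered positions, including the open area at the top of the control grid.

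The HFD section covered more of the capture grid than the control section, 81.3% (95% interval 81.2 to 81.4) against 71.2% (71.1 to 71.3), a ratio of 1.14. The 4 column blocks of the HFD section ranged from 77.8% to 84.5% and those of the control section from 67.5% to 73.0%, so the ranges did not overlap over the whole grid. The control tissue began at row 31, with little of it before row 106, and the HFD tissue at row 0. When only the rows from the first to the last with at least 50% cover were kept, 724 in the control and 826 in the HFD section, the covered share was 81.9% in both, and the column blocks overlapped, at 77.7% to 84.3% in the control and 78.9% to 84.2% in the HFD section. These rows were chosen after seeing the data and by cover itself, so the equality does not tell placement of the tissue from its amount.

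The HFD section had more edge for its area than the control section over the whole grid, but not in every part. Bins at the tissue edge made up 4.90% (95% interval 4.84 to 4.95) of covered bins in the HFD section and 4.31% (4.26 to 4.37) in the control section, a ratio of 1.13. The length of boundary per area of tissue was 7.86 mm per mm² in the HFD and 6.79 mm per mm² in the control section. It was counted along the 8 µm sides between covered and uncovered bins inside the grid. This stepped length is longer than a smooth outline, and it was not among the measures set beforehand. The column blocks of the HFD section ranged from 4.47% to 5.34% and those of the control from 3.11% to 5.16%. Blocks were paired by grid position only, without matching parts of the intestine. By position, the HFD section was higher in blocks 1 to 3 (4.47% against 3.11%, 5.34% against 4.32% and 5.19% against 4.75%) and lower in block 4 (4.59% against 5.16%). Bins deeper than 40 µm made up 74.8% (95% interval 74.7 to 74.9) of the HFD section and 77.2% (77.0 to 77.3) of the control section. The values of their column blocks also overlapped, at 72.4% to 76.8% and 73.6% to 83.1%. The HFD section was lower in blocks 1 to 3 (76.8% against 83.1%, 72.4% against 76.7% and 73.6% against 74.9%) and higher in block 4 (76.5% against 73.6%). The median distance of a covered bin to open space was 91.2 µm in the HFD section and 104 µm in the control section. This median was also not among the measures set beforehand.

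**Figure D2:**
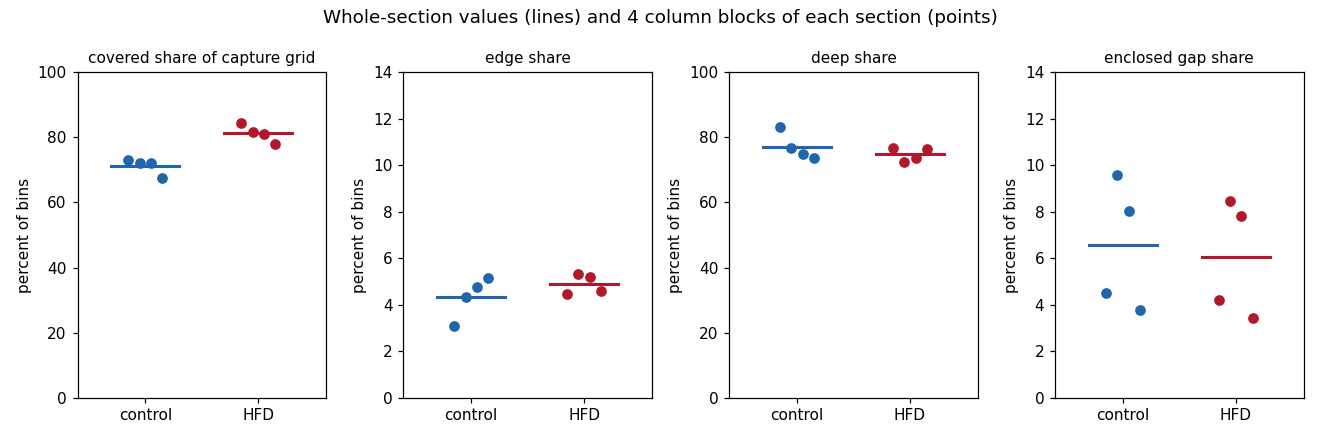
Covered, edge, deep and enclosed gap shares (percent of bins) of each section, with lines for the whole section and points for its 4 column blocks, on axes that start at 0 and differ between panels. Column blocks of the HFD and control sections overlapped for the edge, deep and enclosed gap shares, and not for the covered share of the whole grid, where the lowest HFD block was 77.8% and the highest control block 73.0%. Within the rows from the first to the last with at least 50% cover, the blocks overlapped for the covered share as well.

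Uncovered areas enclosed by covered bins took up 2.35 mm² in the HFD and 2.25 mm² in the control section. As a share of the outline they were 6.03% (95% interval 5.97 to 6.09) and 6.57% (6.51 to 6.64). The column blocks spanned 3.43% to 8.47% and 3.76% to 9.58%. In both sections the 2 outer blocks were lower than the 2 inner ones, and gaps that reach the frame are by definition not counted. Paired by grid position, the HFD section was lower in each of the 4 blocks, at 4.18% against 4.50%, 8.47% against 9.58%, 7.80% against 8.05% and 3.43% against 3.76%. This pairing follows the grid columns only, and parts of the intestine were not matched between the sections. Contact with the frame also differed between the sections. With bins joined 2 by 2, the ratio of HFD to control was 0.991 over the whole grid. The HFD section had more of the smallest gaps. It held 171 enclosed gaps, of which 41 were a single bin, against 130 and 11 in the control section. With single-bin gaps included, the median gap measured 704 µm² against 3904 µm². Gaps of at least 100 bins numbered 42 in the HFD and 52 in the control section. The median gap and the number of these larger gaps were not among the measures set beforehand. No test was possible between single sections. Some gaps have straight borders on the map, and as the calling of tissue bins is not described, gap, edge and depth values describe the called outline, which need not be that of the tissue.

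The HFD section consisted of 5 pieces of at least 100 bins and the control section of 8. Most of the tissue was in few of them. The largest held 73.9% of the HFD bins and the next pieces 13.9% and 11.96%, whereas the 2 largest control pieces held 67.5% and 32.1%. The order of the piece counts depended on the settings. With bins joined 2 by 2 each section had 3 pieces. With at least 1000 bins there were 3 HFD and 2 control pieces, and with at least 10 bins there were 20 and 19.

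The genes over which the diets can be compared were the same in both sections. The gene tables were identical, with 19059 genes each, 13 of them encoded by the mitochondrial genome. Of 21900 protein-coding symbols in the reference, 18731 (85.5%) had a row under the same symbol. Of the 159 entries of the gene lists fixed beforehand, 155 had a row, 75 of 76 among gene functions and 80 of 83 among cell type markers. The counts describe the table as used here. Whether a gene without a row lacked probes, was filtered out later or was listed under another symbol was not examined.

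Genes of fat handling were listed nearly in full. Of 17 genes of fat uptake and chylomicron assembly, 16 had a row. Among them were Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888959), a fatty acid receptor of the cell surface, and Apob (ENSMUSG00000020609, chromosome 12, 7977629 to 8016839), the structural protein of chylomicrons. The gene without a row was Mttp (chromosome 3, 138089855 to 138143418), which encodes the microsomal protein that loads lipid onto Apob, and its expression was not analysed here. All 11 genes of desaturation and elongation were listed, including Scd1 (ENSMUSG00000037071, chromosome 19, 44394450 to 44407709), which converts stearic to oleic acid, and Elovl6 (ENSMUSG00000041220, chromosome 3, 129532386 to 129638495), which elongates palmitic to stearic acid. All 13 genes of fatty acid oxidation and PPAR targets had a row, among them Cpt1a, the carnitine transferase of mitochondrial fatty acid entry, Hmgcs2, an enzyme of ketone synthesis, and Pdk4. The 12 barrier genes, with the claudin Cldn2, the tight junction scaffold Tjp1 and the antimicrobial lectin Reg3g, were complete. So were the 7 genes of the response to endoplasmic reticulum stress, such as Hspa5, the 9 genes of innate lymphoid cells and cytokines, such as Il22, and the 7 genes that mark regions of the gut, such as the ileal bile acid binding protein Fabp6.

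Marker lists of 17 of the 18 cell types were complete. Among them were enterocytes (7 of 7), goblet cells (7 of 7, with the mucin Muc2) and stem cells (5 of 5, with Lgr5 and Olfm4). Enteroendocrine cells (7 of 7), tuft cells (5 of 5) and cycling cells (4 of 4) were complete. So were smooth muscle (5 of 5), fibroblasts (4 of 4), endothelium (3 of 3) and lymphatics (3 of 3). The immune lists of T cells (5 of 5), B and plasma cells (5 of 5) and macrophages (4 of 4) were complete too. The same held for neurons and glia (4 of 4), erythrocytes (2 of 2), adipocytes (3 of 3) and exocrine pancreas (3 of 3). The exception was the Paneth cell, the antimicrobial cell of the crypt base, with 4 of 7 markers. Lyz1, Mmp7, Ang4 and Itln1 had a row. The alpha-defensins Defa17 (chromosome 8, 21655767 to 21656736), Defa22 (chromosome 8, 21162277 to 21163249) and Defa24 (chromosome 8, 21734494 to 21735471) did not. Over the whole family, 4 of 28 protein-coding alpha-defensin genes were listed, namely Defa21, Defa26, Defa28 and Defa35.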

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

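With 1 section per diet no replicate could be left out. Filling gaps of 1 bin or keeping only pieces of at least 100 bins moved no share ratio of HFD to control outside its counting interval (the latter cannot change the piece count), and ignoring letter case left the list entries with a row at 155. Over all alternatives, 14 comparisons kept within limits (the counting interval for shares, 1.5 times for counts), 14 moved and 2 turned. The counting interval treats bins as independent and is narrow, at 0.967 to 0.971 for the deep share ratio. A small shift therefore counts as moved. Joining bins 2 by 2 gave ratios of 1.144 for the covered share, 1.072 for the edge share, 0.982 for the deep share and 0.991 for the enclosed gap share, and 3 pieces in each section (ratio 1). Leaving out the outer 20 rows and columns gave 1.116, 1.169, 0.962 and 0.933 for the same shares. This crop moves the frame inward and does not remove its effect. Keeping only the rows from the first to the last with at least 50% cover, chosen after seeing the data, gave 1 for the covered share. This choice by cover pulls the covered shares together. The same rows gave 1.175 for the edge share and 0.961 for the deep share. Edge and depth were classified anew within these rows, so tissue cut at the first or last kept row was not counted as edge there. The edge share within them was 4.16% in the control section, against 4.31% over the whole grid. In the HFD section it was 4.89% against 4.90%. The higher ratio thus came with a lower control value, and the effect of the cut was not measured apart. The deep share ratio was 0.982 at 24 µm and 0.936 at 80 µm. The ratio of piece counts, 0.625 at 100 bins, was 1.5 at 1000 bins and 1.05 at 10 bins, so the piece counts give no stable direction. The edge share stayed higher and the deep share lower in the HFD section under every alternative run. The number of sections, not of bins, limits these comparisons.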

Other observations

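The tests in this part were all chosen after the maps and the gene table had been seen. In contrast to the alpha-defensins, several families of fat and defence genes were listed in full, among them 9 of 9 fatty acid binding proteins, 15 of 15 apolipoproteins A to E, 5 of 5 long-chain acyl-CoA synthetases (Acsl), 6 of 6 fatty acid transporters of the Slc27a family, 13 of 13 acyl-CoA thioesterases (Acot) and 4 of 4 Reg3 lectins. Of 35 claudins, 31 had a row, and those without one were Cldn25-ps, Cldn34-ps, Cldn34c2 and Cldn34c3. All 40 symbols looked up that begin with Psma to Psmd (proteasome) and all 49 of the form Krt and a number (keratins) had a row. Well-known genes without a row included Actb and Gapdh, both common reference genes, Cx3cr1, a chemokine receptor of macrophages, Gpx4, a peroxidase that reduces lipid peroxides, and the metabolic enzymes Eno1 and Cs. A total of 6 symbols stood on more than 1 row, so a sum by symbol would merge 12 rows.

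Genes named for the ribosome had no rows as a class. None of 91 protein-coding symbols that begin with Rpl or Rps (S6 kinases left out) had a row, nor did any of 78 mitochondrial ribosomal symbols (Mrpl and Mrps), against 85.5% of all protein-coding symbols. The S6 kinase genes, signalling kinases named after their ribosomal substrate, had no row in 10 of 10 cases (Rps6ka1, Rps6kb1 and others), and neither did the related kinase gene Rskr. By comparison, 13 of 13 MAP kinase and 8 of 8 CaM kinase genes were listed. A choice made by the letters of the gene symbol is a candidate explanation, written as a hypothesis from this table alone. The 3 genes looked up for this hypothesis did not all go the same way. The ribosomal components Fau and Rack1, whose symbols lack the shared letters, had a row, and Rskr, whose symbol lacks them too, did not (2 of 3 with a row). These genes are too few to decide it. A choice by full gene name, listing under other symbols, sequence shared with other gene copies and later filtering of rows were not examined. No biological explanation was tested, since the table is the same for both diets.

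Over the whole grid the covered shares of the sections differed by 10.1 percentage points. Within the rows from the first to the last with at least 50% cover they differed by 0.000111 percentage points. The column blocks within these rows ranged over 6.60 points in the control and 5.31 points in the HFD section. The difference over the whole grid therefore lies in the rows left out. Those rows were left out for low cover, and placement of the tissue, its amount and diet were not separated by any test.

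Whether the higher edge share of the HFD section reflects variation along a section was left open. The sections differed by 0.582 percentage points, and the column blocks ranged over 2.05 points in the control and 0.861 points in the HFD section. The HFD block was the higher one in 12 of 16 pairs of an HFD and a control block, which neither separates the sections nor shows them to be alike. Column blocks cut across the tissue bands, so variation between bands was not measured. An effect of diet on the called outline of the tissue stays untested with 1 section per diet, and tissue layers such as the mucosa were not told apart.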
